A study of Homo sapiens with 6 samples.

How the data were processed

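RNA sequencing was done on total RNA of U937 cells, a human myeloid leukaemia line, in 2 groups of 3 libraries: wild-type cells and cells labelled shENO1, read here as carrying a short hairpin RNA against ENO1. Groups and replicate numbers were taken from the submitters' labels. The libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. The deposited table held 1 value per gene and library for 58735 genes, in FPKM (fragments per kilobase of gene model, scaled to library size), as the authors' normalisation with Cuffnorm left it, per the submitters' processing notes. Those notes also named STAR and Cufflinks and the build hg38 (GRCh38); versions, parameters, strand settings and the handling of reads that match several places were not given in the sources used here. All 58735 gene identifiers were found in GENCODE release 29, and 58724 genes had the same start and end there. Coordinates are those of the table, on GRCh38, counted from 1.

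The depth was recovered from the values. FPKM multiplied by the gene length of the table was a whole multiple of 1 step per library for 100% of the values above 0, with a tolerance of 0.001, so that the reads per gene followed from the table. The libraries held 14216739 to 17499636 reads in genes. The recovered reads were used for depth, for shares of reads and for an added test, and the FPKM values as deposited were used for the main test.

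Genes with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model of the 2 groups, empirical Bayes with a mean-variance trend), and p-values were adjusted with the Benjamini-Hochberg method. A gene passed at an adjusted p under 0.05, and every adjusted p below for a gene comes from this test unless another is named. Because 1 is added before the logarithm, log2 fold changes understate the change of genes with low FPKM; fold values in the text are ratios of mean FPKM. Errors after ± are standard deviations over the 3 libraries of a group, and SE is the moderated standard error of the log2 fold change. For ENO1 the text also gives the exact two-sided permutation p and the smallest value that 3 against 3 libraries can give.

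Before the data were examined, 40 gene lists with 923 members were fixed; 892 members were matched by the symbol in the table, 30 through the current symbol and 1 was not matched. The 37 lists with at least 5 tested members were compared with all other tested genes by limma's camera with a preset correlation between genes of 0.01, adjusted over the 37 lists. The same test with a correlation estimated from the residuals was run beside it. limma's fry was also run; it tests whether the members of a list move on balance in 1 direction, against no change, and does not compare them with other genes, so its p-values answer another question than those of camera. Counts of changed members are given over all tested genes and, separately, adjusted over the list alone. The genes named in the text also follow a rule fixed at that time. It took ENO1; the 12 genes with the largest change in each direction, among genes past the threshold with a mean of at least 5 FPKM and no overlap between groups; up to 4 changed members with the largest change from each list past its test or with at least 3 changed members; and the 3 members with the highest mean from the glycolysis list and the lists of other cell types. Clone-named loci were left out of the rule. The other enolase genes and the genes that overlap or host a named gene are given outside this rule; the gene families of the closing section were defined after the list results had been seen, and their named members after their values had been seen.

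Alternatives covered the pseudocount, the filter, the scaling, the prior, the threshold, leaving out each library, and the replicate number as a block. Further ones were added after the data had been seen: limma-voom on the recovered reads, scaling on nuclear genes alone, removal of trends with gene length or GC content, genes of at least 300 bases, and leaving out wild-type replicate 3 and shENO1 replicate 3 together. Replicate numbers were not taken to pair libraries across groups. The tests were tried on simulated reads for the comparison of shENO1 with wild type over 12809 genes, with 200 genes changed in each of 5 rounds: 19.4% of genes changed 1.5-fold, 76.7% of those changed 2-fold and 93% of those changed 4-fold were called, and 5.7% of calls were false. In the same simulation camera called 5 of 5 moved sets and also 1 of 5 unmoved sets. Genes were drawn independently, with 1 spread between libraries for all (dispersion 0.0121) and no library effects. The rates need not hold for the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

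The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The control was labelled wild type, with no control hairpin among the samples, so that ENO1 depletion and the delivery of a hairpin were not separated by the design. Strand was not stated, and reads of overlapping genes on either strand, and of near-identical copies, cannot be assigned with certainty.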

Results

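The transcriptome of U937 cells was measured in 3 wild-type libraries and in 3 libraries of cells with a hairpin against ENO1, the gene of the glycolytic enzyme alpha-enolase. U937 is an established human line that grows as immature monocyte-like cells. Recovered reads in genes numbered 14836584, 15886584 and 14216739 in the wild-type libraries and 15257070, 14845420 and 17499636 in the shENO1 libraries. No library pair looked like a library deposited more than once, since chi-square per degree of freedom between recovered reads of replicates ranged from 3.98 to 41.5. The comparison asks how gene expression differs between cells with a hairpin against ENO1 and wild-type cells.

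ENO1 mRNA fell 5.72-fold in the shENO1 cells. Lists with a lower median included cytosolic heat shock (10 of 15 tested members fell, led by HSPA1A, HSPA1B and DNAJB1), cholesterol synthesis (12 of 22), G2 and mitosis (8 of 26), NF-kB pathway genes (8 of 23) and hypoxia targets (4 of 17); they passed camera with a preset correlation, and had adjusted p = 0.225, 0.234, 0.473, 0.225 and 0.225 with an estimated correlation. MYC mRNA rose 3.53-fold. By the same test, MYC targets and ribosome biogenesis (15 of 28 rose) and S phase and DNA replication (10 of 26) were higher. So were serine and one-carbon metabolism (7 of 14), neutrophil primary granules and early myeloid cells (5 of 14) and mRNAs of the mitochondrial genome (5 of 13). In this order, the lists had camera adjusted p = 0.225, 0.225, 0.368, 0.409 and 0.409 with an estimated correlation. In the mitochondrial list, wild-type replicate 3 had a median deviation of -0.03 from the average of all libraries, against -0.73 and -0.61 in the other wild-type libraries. Other glycolytic enzymes did not move in 1 direction.

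ENO1 (ENSG00000074800, chromosome 1, 8861000 to 8879250, minus strand, GRCh38) was measured at 526, 545 and 561 FPKM in the wild-type libraries and at 91.5, 82.8 and 111 FPKM in the shENO1 libraries. The means were 544 ± 17.4 and 95.1 ± 14.4 FPKM (SD, n = 3 each), so 17.5% of the wild-type level was left. The log2 fold change was -2.51 (SE 0.14, limma adjusted p = 0.00129), on 41006 to 44980 recovered reads per wild-type library and 6636 to 9869 per shENO1 library. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Of the related enolase genes, ENO2 fell from 7.82 ± 1.69 to 4.14 ± 0.296 FPKM (adjusted p = 0.0252), and ENO3 was at 7.27 ± 1.43 and 5.14 ± 0.798 FPKM without passing the test (adjusted p = 0.133). ENO4, the antisense transcript ENO1-AS1 and the processed copies ENO1P1 to ENO1P4 were listed at 0 in all 6 libraries.

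Of 12809 genes tested, 1007 were higher and 828 lower in shENO1 cells (limma, adjusted p under 0.05), so 54.9% of the changes were increases. Protein-coding genes made up 954 of the increases and 547 of the decreases. Changes of at least 1 on the log2 scale were seen in 104 higher and 210 lower genes. The 3 shENO1 libraries lay on 1 side of the 3 wild-type libraries in 4800 genes (37.5%, against 10% by chance). With libraries scaled on nuclear genes alone, 1397 genes were higher and 499 lower, so increases made up 73.7%. That scaling moved the median log2 fold change of all tested genes from -0.017 to 0.081. Increases made up 49.8% (819 higher, 825 lower) with libraries scaled to the same FPKM total. They made up 49.5% (732 higher, 748 lower) without shENO1 replicate 3. The counts depended on single libraries: 147 higher and 134 lower genes were left without wild-type replicate 1, 214 and 159 without wild-type replicate 2, 288 and 266 without shENO1 replicate 1, and 681 and 533 without shENO1 replicate 2. Of 112 named genes past the threshold, 72, 64, 54 and 27 no longer passed without those libraries in the same order, 11 without wild-type replicate 3 and 14 without shENO1 replicate 3.

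**Figure D1:**
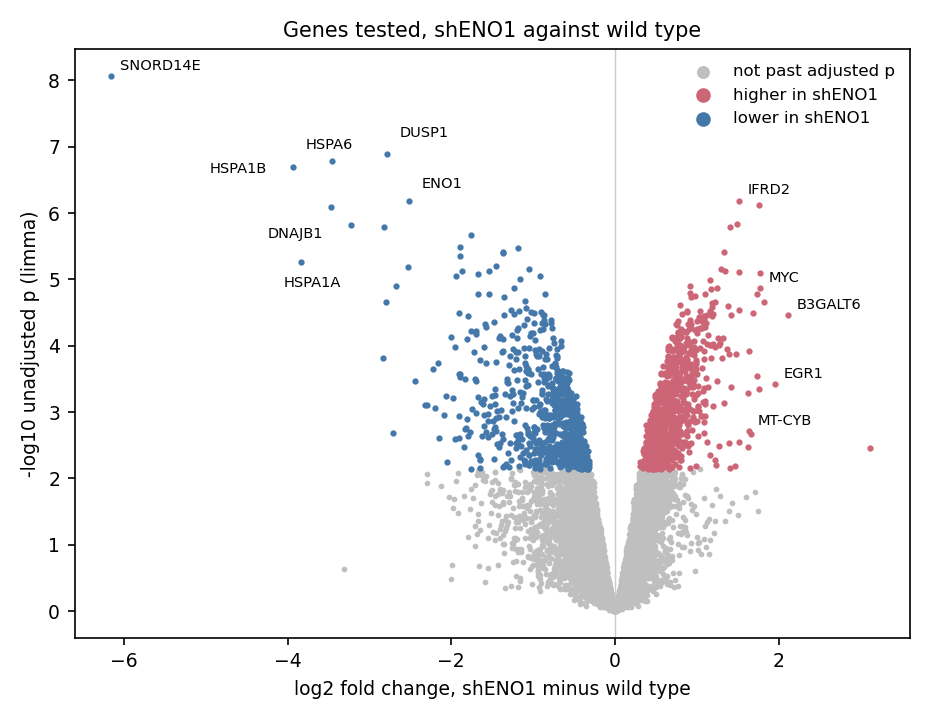
Each point is 1 of the 12809 tested genes, with the log2 fold change (shENO1 minus wild type, on log2(FPKM + 1)) on the x axis and -log10 of the unadjusted limma p on the y axis; red points are the 1007 higher and blue points the 828 lower genes. SNORD14E, at -6.15, lies farthest from 0 on the lower side, and HSPA1B, HSPA1A, HSPA6, DNAJB1, DUSP1 and ENO1 lie between -3.93 and -2.51.

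Principal component 1 held 47.1% of the variance and separated the groups. Component 2 held 27.3% and set wild-type replicate 3 (-32.2) and shENO1 replicate 3 (34.7) at opposite ends. These 2 libraries also had opposite trends with gene length (Spearman rho across protein-coding genes 0.179 and -0.375). The trend did not mark them alone, since the highest rho, 0.254, was that of shENO1 replicate 2. Wild-type replicates 1 and 2 were at 0.013 and -0.11, and shENO1 replicate 1 at 0.058. Without wild-type replicate 3 and shENO1 replicate 3, 1649 genes were higher and 2033 lower. This setting was chosen after these libraries had been seen to lie apart, so a smaller spread within groups was built into it. Calls gained with it, here and below, are therefore no independent evidence. Reads on the mitochondrial chromosome made up 4.02% ± 1.01 of the wild-type and 6.60% ± 0.856 of the shENO1 reads in genes (SD, n = 3), with wild-type replicate 3 at 5.19%.

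**Figure D2:**
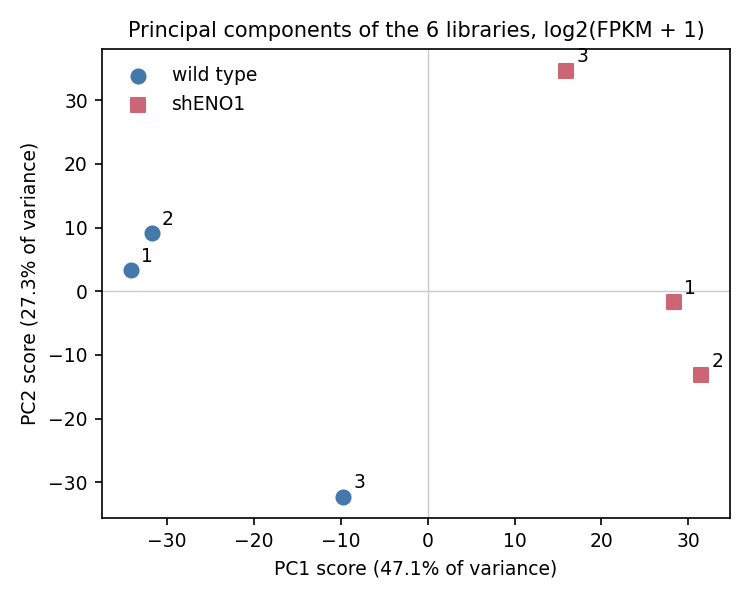
Scores of the 6 libraries on principal components 1 and 2 of log2(FPKM + 1), as circles for wild type and squares for shENO1, with the replicate number beside each point. The groups lie on either side of 0 on component 1, and wild-type replicate 3 (-32.2) and shENO1 replicate 3 (34.7) lie apart on component 2.

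Among cytosolic heat shock genes, which encode chaperones and their partners, 10 of 15 tested members fell and 0 rose (12 and 0 when adjusted over the list alone). HSPA1B, an inducible HSP70 gene, fell from 270 ± 36.2 to 16.9 ± 3.75 FPKM (log2 fold change -3.93, SE 0.18, adjusted p = 0.000651). Its neighbour HSPA1A fell from 189 ± 47 to 12.5 ± 4.94 FPKM (-3.84, adjusted p = 0.00347), and DNAJB1, an HSP40 co-chaperone, from 172 ± 34.5 to 17.4 ± 3.74 FPKM (-3.23, adjusted p = 0.00172). HSPA8, the constitutive HSP70, fell 3.42-fold from 392 ± 29.7 to 115 ± 7.27 FPKM. HSPA6, outside the list, fell 14.9-fold from 37.1 ± 4.74 to 2.49 ± 0.567 FPKM. Over the 15 members the median was -0.97 (camera adjusted p = 3.67e-09), with an adjusted p = 0.225 with an estimated correlation. HSPA1A and HSPA1B are near-identical copies, so the split of reads between them is uncertain.

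Genes of MYC targets and ribosome biogenesis rose in 15 of 28 tested members and fell in 0 (20 and 0 when adjusted over the list alone). MYC itself, on chromosome 8 at 127735434 to 127741434, rose from 19.6 ± 3.45 to 69.1 ± 9.05 FPKM (log2 fold change 1.77, SE 0.16, adjusted p = 0.00445). RRS1, an assembly factor of the large ribosomal subunit, rose from 3.09 ± 0.619 to 10.7 ± 1.53 FPKM, NOP16 from 1.42 ± 0.379 to 5.40 ± 1.22 FPKM, and POLR1B, a subunit of RNA polymerase I, from 3.05 ± 0.358 to 8.43 ± 0.989 FPKM. Over the list the median was 0.63 (camera adjusted p = 6.42e-10, adjusted p = 0.225 with an estimated correlation). Of the 40 cytosolic ribosomal protein genes tested, 0 passed in either direction, with a list median of -0.41 (camera adjusted p = 7.74e-05, adjusted p = 0.682 with an estimated correlation). By fry, this list had an adjusted p = 0.203; shENO1 replicate 3 (median deviation 0.24) lay among the wild-type libraries (-0.03 to 0.38), apart from the other shENO1 libraries (-0.33 and -0.51). The median was -0.21 after quantile normalisation, -0.27 without shENO1 replicate 2, -0.63 without shENO1 replicate 3 and -0.73 without both libraries at the ends of component 2, where 30 members were lower.

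In the list of S phase and DNA replication, 10 of 26 members rose and 0 fell (20 and 0 when adjusted over the list alone), with a median of 0.40 (camera adjusted p = 8.86e-09, adjusted p = 0.225 with an estimated correlation). UNG, a uracil-DNA glycosylase, rose from 12.5 ± 0.719 to 25.2 ± 4.32 FPKM, POLA1 from 9.94 ± 1.02 to 17.9 ± 0.834 FPKM, MCM2 from 29.3 ± 1.98 to 48.5 ± 6.92 FPKM and CCNE1, encoding cyclin E1, from 6.11 ± 0.904 to 9.77 ± 1.36 FPKM. In the list of G2 and mitosis, 8 of 26 fell and 0 rose (11 and 1 when adjusted over the list alone), with a median of -0.29 (camera adjusted p = 0.000207, adjusted p = 0.473 with an estimated correlation). UBE2C, of the anaphase-promoting pathway, fell from 47.6 ± 2.21 to 26.0 ± 1.57 FPKM and PTTG1, encoding securin, from 85.1 ± 5.92 to 53.1 ± 5.48 FPKM. With nuclear scaling the median of this list was -0.18.

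Of 22 replication-dependent histone genes, 5 were tested and 3 fell (5 when adjusted over the list alone), with a median of -0.68 (camera adjusted p = 0.000673, adjusted p = 0.225 with an estimated correlation). These transcripts lack a poly(A) tail, and the list was fixed as a sign of RNA selection as well as of S phase. Which of these lies behind the fall was not tested. HIST1H1C fell from 13.5 ± 2.21 to 4.86 ± 1.35 FPKM and HIST2H2BE from 6.16 ± 0.409 to 2.33 ± 0.293 FPKM. The median of these low genes was -1.30 with a pseudocount of 0.1, -1.11 with libraries scaled to the same FPKM total, -1.41 with limma-voom and -0.45 with no filter on FPKM. Of 19 p53 target and cyclin-dependent kinase inhibitor genes, 6 fell and 1 rose (8 and 2 when adjusted over the list alone), among them GADD45B, from 46.0 ± 4.83 to 21.7 ± 2.91 FPKM, BBC3, from 8.83 ± 0.594 to 4.36 ± 1.41 FPKM, and, upward, AEN, from 2.47 ± 0.32 to 5.2 ± 1.38 FPKM. Their median was -0.27 (camera adjusted p = 0.0231, adjusted p = 0.682 with an estimated correlation); the list no longer passed without shENO1 replicate 2 (-0.23, adjusted p = 0.103) or by fry (adjusted p = 0.109), and its median was -0.17 with a pseudocount of 5. In this list shENO1 replicate 3, at a median deviation of 0.06, stood with the wild-type libraries (0.08 to 0.21) and apart from the other shENO1 libraries (-0.24 and -0.28).

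Cholesterol synthesis genes fell in 12 of 22 tested members and rose in 0 (15 and 0 when adjusted over the list alone). HMGCS1, an early enzyme of the mevalonate pathway, fell 2.10-fold from 121 ± 14.1 to 57.8 ± 8.41 FPKM (log2 fold change -1.06, SE 0.15, adjusted p = 0.00969). STARD4, a sterol carrier, fell from 69.2 ± 3.11 to 33.5 ± 4.56 FPKM and MVD from 71.4 ± 9.18 to 35.8 ± 6.71 FPKM. The list median was -0.52 (camera adjusted p = 1.11e-05, adjusted p = 0.234 with an estimated correlation). In the list of fatty acid synthesis and desaturation, 1 of 13 members fell and 0 rose (the same when adjusted over the list alone, camera adjusted p = 0.331, by fry 0.0216).

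Serine, glycine and one-carbon genes rose in 7 of 14 tested members and fell in 0 (8 and 0 when adjusted over the list alone). PSAT1, an enzyme of serine synthesis, rose from 20.1 ± 1.36 to 34.1 ± 3.32 FPKM, the folate enzymes MTHFD1L and MTHFD1 from 7.04 ± 1.35 to 12.7 ± 0.747 and from 10.9 ± 0.952 to 18.4 ± 1.56 FPKM, and the glutamine transporter SLC1A5 from 40.9 ± 2.17 to 68.5 ± 7.13 FPKM. Their median was 0.51 (camera adjusted p = 0.000119, adjusted p = 0.368 with an estimated correlation).

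In the glycolysis list, which holds other enzymes, transporters and regulators beside ENO2 and ENO3, 2 of 24 tested members rose and 5 fell (3 and 5 when adjusted over the list alone). The monocarboxylate transporter SLC16A1 rose from 10.9 ± 0.606 to 21.5 ± 0.636 FPKM and the hexokinase HK3 from 2.51 ± 0.657 to 6.53 ± 1.64 FPKM, while the glucose transporter SLC2A3 fell from 32.7 ± 0.142 to 20.3 ± 0.554 FPKM. The 3 most abundant members did not pass: GAPDH at 641 ± 30.9 and 537 ± 77.8 FPKM, PKM at 313 ± 6.15 and 329 ± 45.8 FPKM, and PGAM1 at 131 ± 9.94 and 156 ± 24.6 FPKM (adjusted p = 0.285, 0.786 and 0.284). The log2 fold change of PKM, 0.07, was -0.04 without shENO1 replicate 3. GAPDH was lower without both libraries at the ends of component 2 (-0.38, adjusted p = 0.0426), and PGAM1 was higher after quantile normalisation (0.43, adjusted p = 0.0198). The list median was 0.07 and its mean -0.02 (camera adjusted p = 0.942). In the list of other hypoxia targets, 4 of 17 fell and 0 rose (7 and 0 when adjusted over the list alone), including VEGFA, from 26.4 ± 5.59 to 11.1 ± 2.49 FPKM, and BNIP3, from 14.9 ± 1.04 to 10.3 ± 0.432 FPKM. Its median was -0.31 (camera adjusted p = 0.000663, adjusted p = 0.225 with an estimated correlation), and it was -0.20 with nuclear scaling and -0.19 with a pseudocount of 5. In the TCA cycle list 3 of 23 members rose (OGDH, DLAT and DLD) and 0 fell, in the pentose phosphate pathway 1 of 10 rose, and in nuclear-encoded oxidative phosphorylation 1 of 51 rose and 0 fell. Adjusted over the list alone, 3, 2 and 0 members of these lists were higher and 0 lower. None of the 3 lists passed (camera adjusted p = 0.211, 0.284 and 0.664), but the TCA cycle list was higher with no filter on FPKM (median 0.07, camera adjusted p = 0.0253), and the oxidative phosphorylation list was lower without shENO1 replicate 3 (median -0.19, camera adjusted p = 0.00905) and without both libraries at the ends of component 2 (-0.28, camera adjusted p = 0.000425).

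Of the 13 protein-coding genes of the mitochondrial chromosome, 5 rose and 0 fell (6 and 0 when adjusted over the list alone), with a median of 0.83 (camera adjusted p = 0.000259, adjusted p = 0.409 with an estimated correlation). MT-CYB rose from 487 ± 239 to 1422 ± 209 FPKM (log2 fold change 1.64, SE 0.33, adjusted p = 0.0254) and MT-ND2 from 762 ± 362 to 2050 ± 313 FPKM. Wild-type replicate 3 was the highest of its group for MT-CYB, at 763 FPKM against 340 and 358 FPKM. The median was 0.53 after quantile normalisation, where MT-ND1, MT-ND2 and MT-ATP6 no longer passed. The ribosomal RNAs of the same chromosome went the other way: they took 0.901% ± 0.116 of wild-type and 0.730% ± 0.0288 of shENO1 reads (SD, n = 3). MTND2P28, a nuclear copy of MT-ND2 on chromosome 1, rose from 49.7 ± 20.4 to 148 ± 12 FPKM, and reads of the copies cannot be told apart with certainty.

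Genes of neutrophil primary granules and early myeloid cells rose in 5 of 14 tested members and fell in 0 (7 and 0 when adjusted over the list alone). PRTN3, encoding proteinase 3, rose from 196 ± 58.8 to 513 ± 50.7 FPKM (log2 fold change 1.42, SE 0.22, adjusted p = 0.0123), MS4A3 from 29.2 ± 3.05 to 55.7 ± 5.86 FPKM, and the similar ribonuclease genes RNASE3 and RNASE2 from 99.5 ± 9.01 to 199 ± 23.6 and from 219 ± 27.7 to 352 ± 19.9 FPKM. The list median was 0.46 (camera adjusted p = 0.00428, adjusted p = 0.409 with an estimated correlation), and 0.18 with no filter on FPKM. Among monocyte and macrophage genes, 6 of 23 rose and 1 fell (7 and 1 when adjusted over the list alone). The transcription factor gene IRF8 rose from 25.2 ± 1.07 to 45.7 ± 3.25 FPKM, and the integrin gene ITGAX fell from 7.97 ± 0.181 to 4.55 ± 0.553 FPKM. This list did not pass (camera adjusted p = 0.0782), but passed without wild-type replicate 2 (median 0.21, camera adjusted p = 0.0384) without shENO1 replicate 2 (0.35, camera adjusted p = 0.0354), with no filter on FPKM (0.22, camera adjusted p = 0.000359) and by fry (adjusted p = 0.0302). In the list of leukaemia stem and progenitor genes, MYB and SOX4 rose and MEIS1 and IL3RA fell, of 17 tested (4 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.645).

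Cytokine, chemokine and NF-kB pathway genes fell in 8 of 23 tested members and rose in 1 (9 and 2 when adjusted over the list alone). The NF-kB inhibitors NFKBIA and TNFAIP3, themselves NF-kB targets, fell from 52.3 ± 3.84 to 25.9 ± 2.22 and from 26.9 ± 1.55 to 14.1 ± 0.834 FPKM, and CXCL10 from 6.39 ± 1.06 to 2.64 ± 0.473 FPKM. The list median was -0.36 (camera adjusted p = 0.000663, adjusted p = 0.225 with an estimated correlation), and -0.24 with no filter on FPKM. Immediate early genes were divided, with 5 of 20 higher and 7 lower (5 and 7 when adjusted over the list alone). As a list they did not pass against other genes (camera adjusted p = 0.349). EGR1 rose from 14 ± 2.02 to 60.2 ± 22.9 FPKM, while DUSP1, a phosphatase of MAP kinases, fell 7.95-fold from 44.0 ± 3.87 to 5.53 ± 0.785 FPKM and KLF6 fell from 53.9 ± 4.53 to 24.8 ± 1.93 FPKM. In the interferon-stimulated list 4 of 25 rose and 0 fell, SAMD9 from 1.81 ± 0.103 to 5.11 ± 0.764 FPKM (4 and 0 when adjusted over the list alone, list camera adjusted p = 0.234, by fry 0.0302).

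In the unfolded protein response, 3 of 20 members fell and 0 rose, with the same counts when adjusted over the list alone. HSPA5, the HSP70 of the endoplasmic reticulum, fell from 456 ± 18.1 to 247 ± 19.9 FPKM, and HSP90B1 from 328 ± 13 to 223 ± 21.5 FPKM. The median was -0.24 (camera adjusted p = 0.0287, adjusted p = 0.428 with an estimated correlation). The list no longer passed after quantile normalisation (-0.21, adjusted p = 0.0966), without wild-type replicate 3 (-0.23, adjusted p = 0.0664), without shENO1 replicate 1 (-0.23, adjusted p = 0.0644) or without shENO1 replicate 2 (-0.20, adjusted p = 0.0573), and its median was -0.13 with nuclear scaling. ATF4 and integrated stress response targets were divided, with 4 of 24 higher and 3 lower (6 and 5 when adjusted over the list alone, camera adjusted p = 0.793). The amino acid transporter SLC7A5 rose from 9.84 ± 1.3 to 23.6 ± 1.65 FPKM, and PPP1R15A and DDIT4 fell from 140 ± 33.5 to 45.6 ± 15.4 and from 57.9 ± 0.475 to 25.3 ± 3.48 FPKM.

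The list of RNA polymerase III and small RNA host transcripts had 5 tested members, of which 4 fell (4 when adjusted over the list alone), with a median of -1.37 (camera adjusted p = 0.00266, adjusted p = 0.464 with an estimated correlation). The 4 were the nuclear long RNAs MALAT1, from 63.8 ± 15.2 to 22.3 ± 2.3 FPKM, and NEAT1, from 58.3 ± 21.3 to 20.9 ± 2.85 FPKM, and the snoRNA host genes GAS5 and SNHG1. None of these is known as a product of RNA polymerase III. Wild-type replicate 3 stood nearer to the shENO1 libraries in this list, with a median deviation of 0.12 from the average of all libraries against 0.90 and 0.97 in the other wild-type libraries. Of 125 tested snoRNAs 20 fell and 0 rose, and of 164 sense-intronic transcripts 24 fell and 1 rose. Those named SNORA or SNORD, a family defined after the data had been seen, had 13 of 88 lower and 0 higher (median -0.759, camera adjusted p = 5.01e-06, adjusted p = 0.214 with an estimated correlation). SNORD14E, an 85-base snoRNA within HSPA8 on the same strand, fell from 292 ± 25.1 to 3.18 ± 0.962 FPKM (log2 fold change -6.15, SE 0.18, adjusted p = 0.00011). MIR3153 within CKS2, SNORA31 within TPT1 and SNORA11 within MAGED2 fell 11.4-, 4.71- and 5.05-fold, with log2 fold changes of -1.23, -0.507 and -0.426 for these hosts. RNU6-548P, a U6 copy within SLC1A4 on the same strand, fell 4.59-fold while SLC1A4 rose (log2 fold change 0.616). SNORA31, SNORA11 and RNU6-548P rested on few reads, with means of 35.7, 18.7 and 24.3 per wild-type library and 8, 4 and 5.67 per shENO1 library. Reads at such short loci can come from the transcripts around them.

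Other genes with the largest changes belonged to no list above. B3GALT6, a galactosyltransferase of proteoglycan synthesis, rose from 3.77 ± 1.28 to 19.5 ± 3.94 FPKM (log2 fold change 2.12, SE 0.22, adjusted p = 0.0056). HS3ST2, a heparan sulfate sulfotransferase, rose from 8.72 ± 2.72 to 28.8 ± 3.9 FPKM, ALDH1B1, a mitochondrial aldehyde dehydrogenase, from 4.54 ± 0.791 to 14.7 ± 3.74 FPKM, and IFRD2 from 7.54 ± 0.286 to 23.4 ± 1.24 FPKM. PPP1R10 rose 3.62-fold, and VCX, which has close copies on chromosome X, rose 3.66-fold. CD52, a leukocyte surface glycoprotein, fell from 11.5 ± 1.51 to 2.36 ± 0.766 FPKM. IFRD2 overlaps HYAL3 on the same strand, so part of its reads can belong to the partner under any strand setting. PPP1R10 overlaps MRPS18B, CD52 overlaps UBXN11 and DNAJB1 overlaps TECR on the opposite strand, where this holds if strand was not used.

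**Figure D3:**
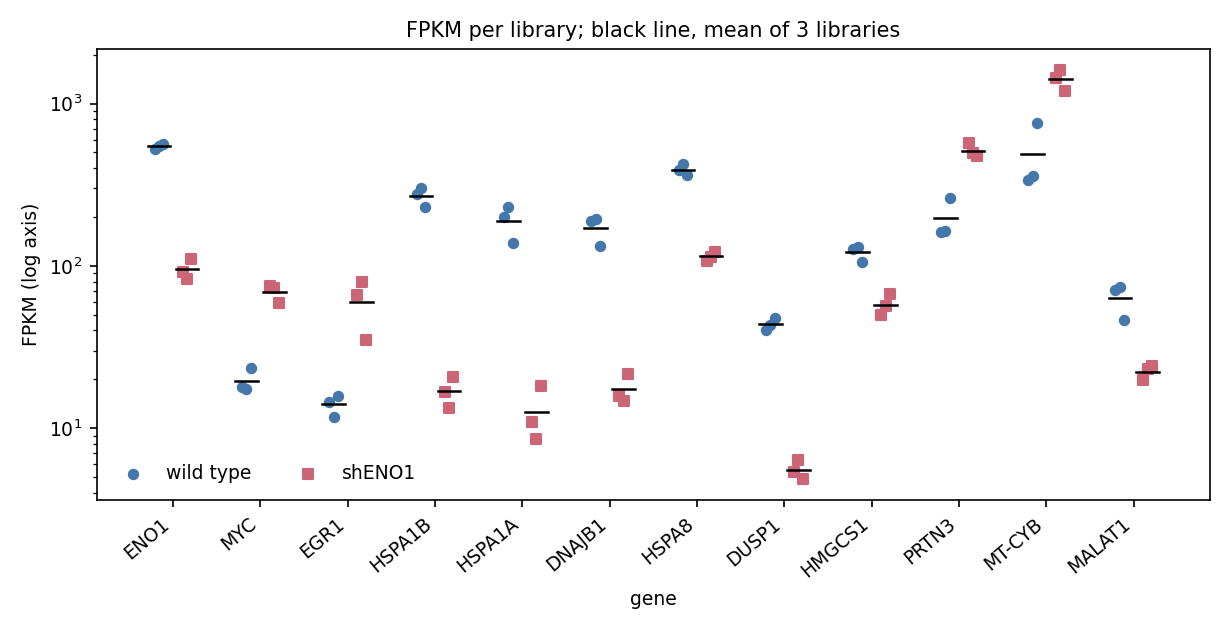
FPKM of 12 genes in each library, on a log axis, as circles for wild type and squares for shENO1; the black lines are the means of 3 libraries. ENO1 lay at 544 and 95.1 FPKM, HSPA1B at 270 and 16.9 FPKM and MYC at 19.6 and 69.1 FPKM on average. In all 12 genes the libraries of the groups did not overlap, which for most of them was a condition of the rule that named them.

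The remaining lists did not pass (camera adjusted p = 0.074 to 0.995). In the list of immune checkpoint genes 3 of 12 rose, among them SIRPA and PVR, and TNFSF9 fell; this list, with a camera adjusted p = 0.074, was higher with no filter on FPKM (median 0.058, camera adjusted p = 0.00471) and by fry (adjusted p = 0.00486). Of the apoptosis regulators 1 of 20 rose (BCL2L11) and 3 fell (BMF, BIRC3 and BIRC2). Of the iron handling genes 3 of 14 rose (STEAP3, SLC40A1 and IREB2), and of the adhesion genes 4 of 21 rose, SELPLG and CCR1 among them, and 1 fell. The antigen presentation lists had 1 of 15 class I members higher and 1 of 7 class II members lower. The lists of NRF2 targets, fatty acid oxidation, gluconeogenesis and glycogen, Notch and Wnt readouts, and lysosome and autophagy had 1 of 19, 1 of 15, 2 of 10, 2 of 9 and 1 of 27 members higher, and 0, 0, 0, 0 and 2 lower. Adjusted over the list alone, higher and lower members were 4 and 1 for checkpoint, 2 and 3 for apoptosis, 6 and 1 for iron, 6 and 2 for adhesion, 1 and 0 for class I and 0 and 2 for class II genes. In the last 5 lists they were 0 and 0, 1 and 0, 4 and 0, 2 and 0, and 4 and 4. Without both libraries at the ends of component 2, the apoptosis list was lower (median -0.24, camera adjusted p = 0.0439) and the Notch and Wnt list higher (0.31, camera adjusted p = 0.029).

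**Figure D4:**
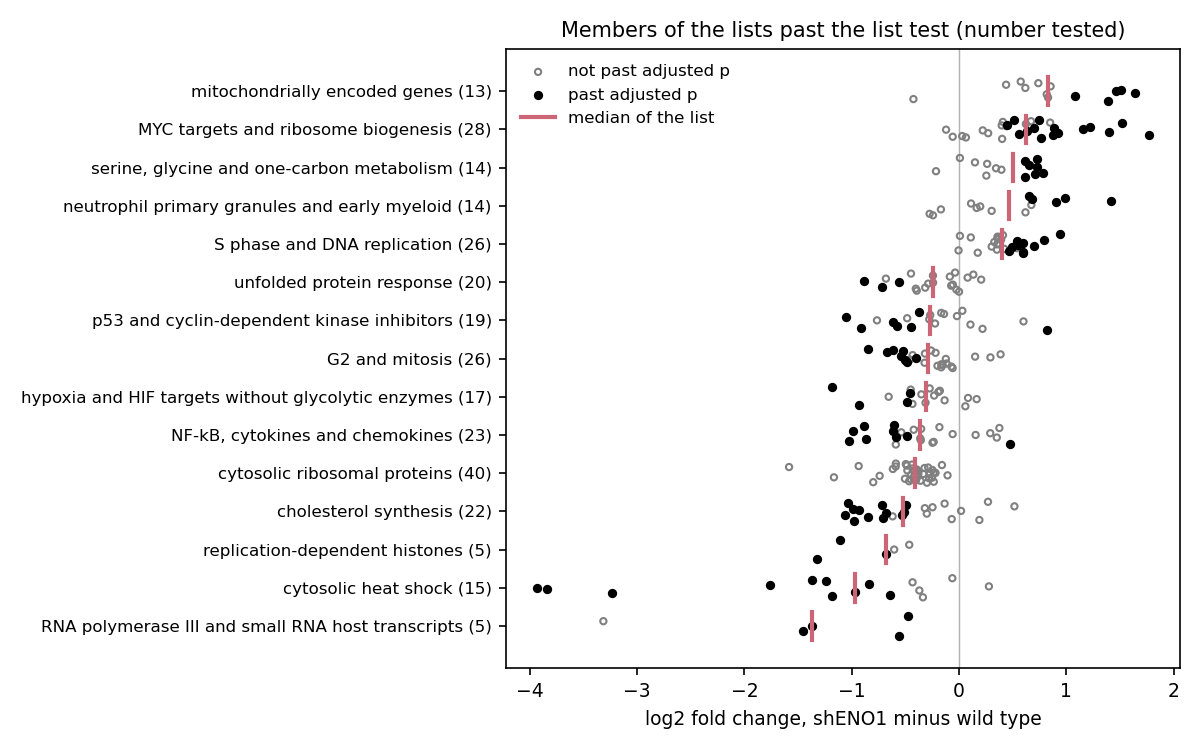
Log2 fold change (shENO1 minus wild type) of each tested member of the 15 lists past the camera test, with the number tested in parentheses; filled points passed the gene test, open points did not, and the red line is the list median. Medians ran from -1.37 for RNA polymerase III and small RNA host transcripts to 0.83 for mitochondrially encoded genes.

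In the T and NK cell list 0 of 5 tested members passed, also when adjusted over the list alone (camera adjusted p = 0.84). Its most abundant members NKG7 (274 ± 20.3 and 261 ± 55.6 FPKM) and CD4 (122 ± 2.12 and 113 ± 13.1 FPKM) had adjusted p = 0.769 and 0.568, and GZMB was at 3.09 ± 0.315 and 2.23 ± 0.578 FPKM. The signs of the small log2 fold changes of NKG7 and CD4 differed between scalings: NKG7 was at -0.09 and at 0.20 after quantile normalisation, and CD4 at -0.11 and at 0.02. Of the B cell markers, CD79A was at 6.94 ± 1.18 and 4 ± 1.39 FPKM (adjusted p = 0.0816), EBF1 at 1.62 ± 0.481 and 2.64 ± 0.462 FPKM (adjusted p = 0.114), and PAX5 rose from 1.5 ± 0.244 to 3.52 ± 0.189 FPKM (adjusted p = 0.00951). COL1A1 led the epithelial and fibroblast list with 1.4 ± 0.103 and 0.993 ± 0.306 FPKM, ahead of ACTA2 (0.695 ± 0.188 and 0.592 ± 0.053) and TAGLN (0.518 ± 0.228 and 0.462 ± 0.126), and 12 of 21 erythroid and megakaryocyte markers were listed at 0 in all libraries. Of that last list, EPOR, the erythropoietin receptor gene, rose from 1.18 ± 0.0883 to 2.13 ± 0.24 FPKM (adjusted p = 0.0404), TFR2 was at 1.41 ± 0.158 and 2.13 ± 0.181 FPKM (adjusted p = 0.0847), KLF1, chosen after its values were seen and below the level tested, at 0.234 ± 0.0734 and 0.764 ± 0.154 FPKM, and GP1BA at 2 ± 0.447 and 1.54 ± 0.301 FPKM.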

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

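The settings that use limma-voom, nuclear scaling, length or GC trends, genes of at least 300 bases, or leave out both replicates 3 were chosen after the data had been seen. Of the 118 named genes, 112 passed in the main fit, mostly as a condition of being named. All settings reuse the same libraries, so a kept direction was largely fixed by that selection. In any setting, 0 named genes turned around past the threshold. Of 2223 values of the named genes, 1798 kept their direction and side of the threshold, 415 lost their call, 2 (GAPDH and PGAM1) gained one and 8 changed sign. The 8 belonged to genes that never passed: with 1 library left out, PKM ranged from -0.0416 (shENO1 replicate 3) to 0.1522 (shENO1 replicate 2), and it was at -0.0373 without both replicates 3 and highest, at 0.3062, after quantile normalisation; NKG7 ranged from -0.2408 to 0.0705 without the same libraries and was at 0.196 after quantile normalisation, 0.0249 with nuclear scaling and 0.0616 without the length trend; CD4 at 0.0247 after quantile normalisation and 0.0053 with nuclear scaling. Of 774 list values, 739 stayed, 22 lost a call, 13 gained one and 0 turned past the threshold.

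The counts of higher and lower genes (1007 and 828) were 445 and 381 with no filter on FPKM, which tests more genes, and 1649 and 2033 without both replicates 3. Nuclear scaling gave 1397 and 499. The narrower criteria gave 104 and 210 with a log2 fold change of at least 1, 177 and 126 at an adjusted p of 0.01, and 12 and 24 for changes beyond 1.5-fold by limma's treat. Leaving out 1 library gave 147 to 914 higher and 134 to 775 lower genes; fewer samples enter these fits. limma-voom gave 1333 and 990, with 1737 of the 1835 calls shared and 0 opposite. Apart from the replicate number as a block, given in the next paragraph, the other settings stayed within 1.5 times of both counts. Nuclear scaling moved the median log2 fold change of all tested genes from -0.017 to 0.081, which turns the counts toward higher genes. More calls without both replicates 3 were to be awaited, since the libraries that lay apart within their groups were the ones left out. Why these libraries lay apart was not tested. Of the lists, 5 were higher and 10 lower; 8 were higher with no filter, while 0 were higher and 0 lower with an estimated correlation, where camera gave unadjusted p values of 0.0144 to 0.39 for the 15 lists. fry, which tests lists against no change and not against other genes, called 8 higher and 9 lower.

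With the replicate number as a block, limma called 0 higher genes and 1 lower gene, with 3081 genes at an unadjusted p under 0.05, and ENO1 had a log2 fold change of -2.51 (adjusted p = 0.0713; 2.73e-05 to 0.0186 in its other alternatives). Deviations from the group means of libraries with the same number correlated at -0.085, -0.334 and -0.459 across genes, so the numbers did not pair the libraries. Not every library correlated best with its own number. Count models on the recovered reads (edgeR and DESeq2) were planned and not run, since the deposited unit is FPKM. In the simulation, small changes were found least often: 19.4% of 1.5-fold and 93% of 4-fold changes were called. The shares of depth, spread and number of libraries in this were not separated. The simulated genes were independent, with 1 spread for all and no library effects, so the rates need not hold for the real libraries.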

Other observations

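Tests chosen only after the result was seen were those of the gene families below, the summed HSPA1A and HSPA1B reads, the immediate early genes, the olfactory receptor level, the loci with unchanged hosts as evidence against host reads, the mitochondrial ribosomal RNA and the list median without wild-type replicate 3. The scaling tests below also used settings chosen after the data had been seen. These were nuclear scaling for both lists, and the length and GC trends for the heat shock list. Beyond the fixed lists, 28 gene families defined by symbol were compared with all other genes (camera, adjusted over the 28); 9 passed, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. Aminoacyl-tRNA synthetases, which charge tRNAs, rose in 10 of 34 tested members and fell in 0 (median 0.25, adjusted p = 0.000196, adjusted p = 0.441 with an estimated correlation). The mitochondrial enzyme MARS2 rose from 7 ± 0.454 to 14.2 ± 0.589 FPKM, and the cytosolic VARS from 16.9 ± 2.09 to 34.5 ± 3.45 FPKM. Ribosome biogenesis factors named UTP, NOL, NOC or RRP rose in 12 of 32 and fell in 1 (median 0.41, adjusted p = 1.21e-05, adjusted p = 0.214 with an estimated correlation). RNA polymerase subunits rose in 5 of 30 and fell in 0 (median 0.16, adjusted p = 0.0381, adjusted p = 0.705 with an estimated correlation), and POLR1A rose from 1.42 ± 0.0787 to 5.10 ± 0.288 FPKM. tRNA methyltransferases rose in 4 of 16 and fell in 0 (median 0.37, adjusted p = 0.0183, adjusted p = 0.441 with an estimated correlation). Nucleoporins rose in 2 of 21 and fell in 0 (median 0.298, adjusted p = 0.000515, adjusted p = 0.658 with an estimated correlation), zinc finger ZNF genes rose in 26 of 259 and fell in 3 (0.084, adjusted p = 0.0265, adjusted p = 0.214 with an estimated correlation), and mitochondrial ribosomal protein genes rose in 6 of 79 and fell in 1 (0.114, adjusted p = 0.0275, adjusted p = 0.839 with an estimated correlation). These families overlap in part with the fixed lists.

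Metallothioneins, small metal-binding proteins, fell in 3 of 5 tested members and rose in 0 (median -0.83, adjusted p = 0.00172, adjusted p = 0.441 with an estimated correlation). MT2A fell from 195 ± 54.5 to 57.4 ± 8.01 FPKM and MT1X from 7.16 ± 0.0911 to 2.60 ± 0.587 FPKM; members of this family are similar in sequence. Genes with proteasome subunit symbols (41 tested, with PSMA2 and PSMA6 lower and 1 higher, the non-coding PSMB8-AS1, which is no subunit) and the chaperonin CCT subunits (0 of 8 in either direction) did not pass (adjusted p = 0.883 and 0.708), beside the fall of the cytosolic heat shock genes. The medians of the families named as changed kept their sign under quantile normalisation and under scaling to the same median, to the same FPKM total and on nuclear genes.

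The count of 1835 changed genes was set against the other splits of the 6 libraries into 3 and 3. Of the 10 splits, 1 gave as many genes, the real one, and the highest of the others gave 234; with 10 splits a share under 0.05 cannot be reached. The split with 234 genes set wild-type replicates 1 and 2 with shENO1 replicate 3, as component 2 does.

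The fall of HSPA1A and HSPA1B could not come from reads moved between them, since each fell and their summed reads fell by 3.99 on the log2 scale (SE 0.286). This does not bear on the other heat shock genes. The scalings tried do not account for the fall of the list, whose median was at most -0.738 under them. They put the median of all tested genes at -0.055 to 0.081, so none could have brought a list median of -0.97 near 0. The comparison therefore says little about scaling in general. A stress at harvest or in culture that differed between the groups stays open, since the labels give no shared harvest day; the immediate early list, which such a stress may also move, had a median of -0.095 with members in both directions, and of -0.454 (genes of at least 5 FPKM) to -0.008 (nuclear scaling) over the alternatives. An effect of ENO1 depletion or of the hairpin stays open as well, and the design does not separate these.

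Of 1365 tested small RNA, sense-intronic and antisense loci, 180 fell and 18 rose in shENO1 cells, and the median of all was -0.41. The class was not tested as a set. A fall was not particular to it: of 564 processed pseudogenes, outside this class, 47 fell and 4 rose (median -0.247). Over all 2777 tested genes that are not protein-coding, these loci included, 281 fell and 53 rose. Genomic DNA in the wild-type libraries is argued against: reads on olfactory receptor genes were 1.24 times as frequent in wild type, with overlapping libraries, and reached at most 0.00779 FPKM, against a median loss of 3.27 FPKM at the lower loci. For host transcripts, a Spearman rho of 0.2 between the fold changes of 80 called same-strand loci and their hosts decides nothing. Host reads that follow the value of the host gene do not account for the whole pattern. That value is taken over the gene model, so reads of unspliced host transcripts are not excluded. The 685 loci whose host (either strand) moved by under 0.25, called or not, had a median of -0.46 and a share of 0.19 above 0. Without shENO1 replicate 3 these were -0.41 and 0.26. A lower share of unspliced or nuclear RNA in the shENO1 libraries, from the cells or from the RNA preparation, stays open: it would give such a median, but so would any other cause that lowers these loci, and the value is close to that of the whole class.

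The rise of the mitochondrially encoded mRNAs was set against scaling on nuclear genes alone, where the list median was 0.95. This scaling could not remove the rise, since leaving out the risen mitochondrial genes lifts all shENO1 values against wild type. With it, the median of all tested genes moved from -0.017 to 0.081. After quantile normalisation the list median was 0.53, the lowest over the alternatives. A rise of all mitochondrial transcripts alike in the libraries is argued against by the ribosomal RNA. The summed MT-RNR1 and MT-RNR2 reads were at -0.31 (SE 0.13), below the median of 0.83 of the 13 mRNAs. Such a rise in the cells is not decided by this, since a difference in RNA selection was not tested. Of the mitochondrial tRNAs, 3 of 19 rose and 0 fell. Their median was 0.481 (camera adjusted p = 0.0814, adjusted p = 0.441 with an estimated correlation). Wild-type replicate 3, at a median deviation of -0.03, lay between the other wild-type libraries (-0.73 and -0.61) and the shENO1 libraries (0.45 to 0.6), so a higher list median without it, 1.124, was bound to follow and tests nothing. How far the size of the rise rests on the spread of the wild-type libraries stays open, as does a difference in RNA selection between the library preparations, which was not tested. A shift between mitochondrial mRNA and ribosomal RNA (the tRNAs were not tested against either) in shENO1 cells stays open beside these.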
